A study of Mus musculus with 6 samples.

How the data were processed

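Prospective lens tissue of 6 mouse embryos at embryonic day 9.5, 3 wild type and 3 Pax6 knockout, was measured, 1 array per embryo. Per the labels' protocols, frozen embryos were sectioned at 10 micrometres, the lens placode was cut out by laser microdissection, and cDNA amplified from 15 ng of RNA was labelled with biotin. Each embryo is 1 replicate. The array positions in the labels put all 6 arrays on 1 BeadChip, with the genotypes alternating, so slide is no batch here. The labels name a mixed strain background and give no sex.

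The deposited signal table holds linear intensity, the mean bead brightness of each of 46632 probes, exported with GenomeStudio per the submitters' processing notes (its version is not given in the sources used here). The lowest signals were 21.8 to 25.8 on the 6 arrays and their quantiles differed, so these intensities had been neither background-subtracted nor normalized between arrays by the authors. The same deposited table gives a detection p-value per probe and the number of beads averaged, a count with a median of 36 or 37 per array and a minimum of 8 to 12. The authors' second deposited table holds intensity that is linear and background-subtracted, with medians of 7.49 to 7.51 and minima of -14.8 to -13.3, in rank order with the signal of each array (Spearman correlation 1). It was used only as an alternative, and its method is not given in the sources used here.

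Gene symbols came from GEO's platform annotation of the array. 29976 probes had 1 symbol, 10 had several and 16646 were unnamed here, and the latter 2 kinds were given no gene name. The Entrez identifiers of 29921 probes were found in the RefSeq gene table of the assembly GRCm38.p6, which was used for current symbols and for X or Y linkage. No build is named for the array, so no coordinates are given.

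Signals were background-corrected with normexp from the detection p-values, with an offset of 16, quantile normalized and brought to log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 3 arrays were kept, 19381 in all. For a gene with several such probes, the probe with the highest mean over all 6 arrays stood for the gene, and unnamed probes stood alone. This gave 9618 genes and 5068 unnamed probes, 14686 in all. Genotype was tested with lmFit and eBayes with a trend of the variance on intensity, and Benjamini-Hochberg adjustment over all 14686 at 5%. Adjusted p-values of the dimmer pair of Pax6 probes come from the same fit with every probe tested. The replicates are embryos, so the p-values of genes rest on the spread between embryos, with variances shared in part across genes. The main gene list test described below compares the genes of a list with the other genes. Its p-values therefore do not measure the spread between embryos alone. An exact permutation test of 3 against 3 cannot give a two-sided p under 0.10, and none was used in place of the model. A gene undetected on every array of a genotype has only a bound there. Its fold is given as at least the brighter group's mean over the dim group's mean of, per array, the higher of the probe's own value and the lowest value of a detected probe, at the offset used.

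Before the data were examined, the design, the alternatives, 24 gene lists and the rule for named genes were fixed. The rule took every Pax6 probe, the 12 largest rises and the 12 largest falls among genes past the threshold whose 3 knockout values all lay on 1 side of the 3 wild type values, and, where fewer than 12 passed, the genes with the smallest p in that direction. Genes with predicted-model names were left out. From each list it took up to 4 members with the smallest p, and it took the sex-linked check genes. The sex-linked list was not tested as a list. The other 23 lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over the list alone.

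Alternatives were no filter, a stricter filter (detection p under 0.01 on all 3 arrays of a genotype), no background correction, an offset of 50, the authors' normalized table, median scaling, no variance trend, robust variance, array weights, the mean of a gene's probes, every probe tested, the replicate number as a block, and leaving out each array. Runs without X- and Y-linked genes and camera with a variance trend were added after the data were seen. The fit was tested on simulated data of the size of the comparison (14686 genes, 200 of them changed, 10 simulations). It recovered 34.4% of genes changed by a log2 of 1 and 91.9% of genes changed by 2, with 4.46% false calls among its calls and 0 calls without changed genes. The 5 of 20 simulated lists of 20 genes that were shifted by 0.5 were all recovered. Simulated genes varied independently of each other, with the fitted variances. The recovery and the share of false calls hold for that setting and for 200 changed genes. Neither they nor the lists were tested where genes are correlated.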

Results

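The study asked which genes depend on Pax6, a paired-domain transcription factor needed for lens formation, in the lens placode of the mouse embryo. The placode is the thickened head ectoderm from which the lens arises. RNA came from laser-microdissected prospective lens tissue of 3 wild type and 3 Pax6 knockout embryos at embryonic day 9.5. Tissue of both eyes of an embryo was measured on 1 Illumina BeadArray, so the 3 values of a genotype are 3 embryos. The median raw signal of an array was 41.7 in knockout 1 and between 47.3 and 49.8 on the other 5 arrays. Between 38.8% and 41.6% of the 46632 probes were detected per array. Pearson correlations between arrays across probes were 0.932 to 0.949 within wild type, 0.916 to 0.946 within knockout and 0.904 to 0.941 between genotypes, and no array duplicated another. Knockout 1 stood apart on the first principal component, which held 30.3% of the variance, at 55.6 against -25.9 to 2.06 for the other 5 arrays. The number of arrays limits the precision of every value. Values below are normalized log2 intensities as mean ± SD (n = 3 embryos per genotype), and changes are knockout minus wild type with their standard error (SE).

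Pax6 itself was lower in knockout by all 3 of its probes, but by a modest amount that did not pass the test. The brightest probe read 10.05 ± 0.33 in wild type and 9.31 ± 0.31 in knockout, a 1.67-fold difference (log2 change -0.74, SE 0.21, limma adjusted p = 0.428). The second probe differed by -0.66 (SE 0.22, adjusted p = 0.528) and the third by -0.41 (SE 0.32, adjusted p = 0.876). With the first pair of probes the 3 knockout values lay below the 3 wild type values, and with the third probe the groups overlapped. Knockout 1 was lowest by all 3 probes. The third probe read 7.37 in knockout 1, but 8.59 and 8.60 in knockout 2 and 3, within the wild type range of 8.45 to 8.77. All 3 probes were detected on all 6 arrays. The labels do not give the deleted part of the gene, so a probe may lie outside it and then checks nothing about the labels.

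**Figure D1:**
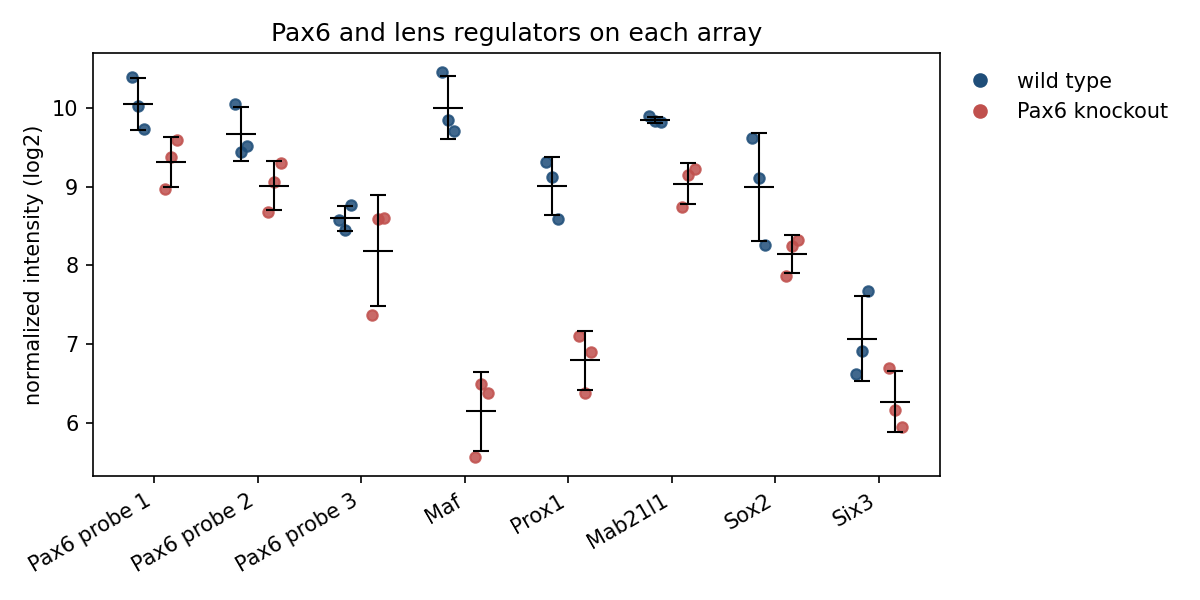
Normalized log2 intensity (vertical axis) of the 3 Pax6 probes and of 5 lens regulators on each array. Points are single embryos, horizontal bars are means of 3 and whiskers are SD. The 3 knockout values of Maf and Prox1 lie below the 3 wild type values by at least 1.49.

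Xist and the 3 Y-linked check genes separated the genotypes completely. Xist, the noncoding RNA that silences the inactive X chromosome of female cells, read 9.34 ± 0.13 in wild type and was detected by its brightest probe on 0 of 3 knockout arrays, a fall of at least 18.2-fold (limma adjusted p = 0.000967). Kdm5d, a histone demethylase encoded on Y, was detected on 0 wild type and 3 knockout arrays and rose at least 2.11-fold (adjusted p = 0.0448), a call that was lost with, among others, median scaling (adjusted p = 0.0916) and no variance trend (0.0664). The Y-linked Eif2s3y was 1.93 higher in knockout (SE 0.28, adjusted p = 0.0601) and was also detected on 2 wild type arrays. Uty was 2.72 higher (SE 0.59, adjusted p = 0.221) and was detected on 1 wild type array, wild type 2, at 6.56 against 4.83 and 4.85 on the others, and with a background offset of 50 its fold was 1.65 times smaller. Neither passed the threshold. Folds given as at least hold for the background offset of 16: with an offset of 50, 13 of 14 named genes with such a bound had a fold below it, 10.1 for Xist and 1.76 for Kdm5d. The labels give no sex. Xist and the Y-linked genes divide the 6 arrays exactly as genotype does, so in every comparison that follows a difference by genotype cannot be told apart from a difference by sex.

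**Figure D2:**
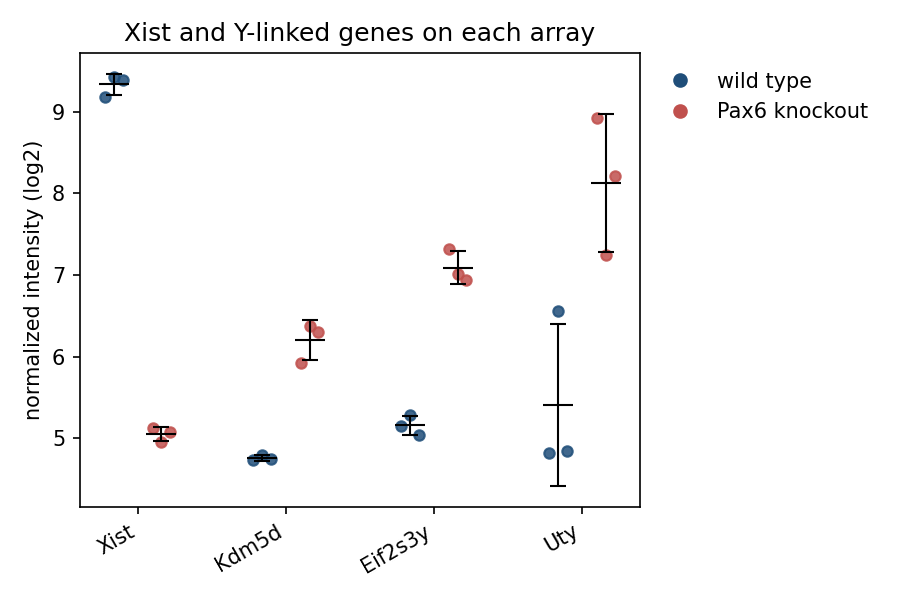
Normalized log2 intensity (vertical axis) of Xist and 3 Y-linked genes on each array, with points for single embryos, bars for means of 3 and whiskers for SD. Xist lies near 9.34 in wild type and near the background in knockout, and the Y-linked genes are higher in knockout.

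Away from the sex chromosomes, the lens transcription factors Maf and Prox1 fell steeply in Pax6 knockout. Maf, a basic leucine zipper factor that activates crystallin genes, read 10.00 ± 0.40 in wild type and 6.14 ± 0.50 in knockout, 14.5-fold lower (log2 change -3.86, SE 0.31, adjusted p = 0.00477). Prox1, a homeobox factor needed for elongation of lens fibre cells, read 9.01 ± 0.37 and 6.79 ± 0.37, 4.65-fold lower (log2 change -2.22, SE 0.28, adjusted p = 0.0337). Phlda1, a pleckstrin homology-like domain protein, fell 3.57-fold (log2 change -1.83, SE 0.13, adjusted p = 0.00313). Slc2a3, a glucose transporter, rose 1.96-fold, from 9.82 ± 0.18 to 10.79 ± 0.07 (adjusted p = 0.0410). The call of Prox1 was lost with no filter on dim probes (adjusted p = 0.106) and without the variance trend (0.0630). The call of Slc2a3 was lost with median scaling (adjusted p = 0.317), without the variance trend (0.168), with no filter on dim probes (0.0995) and with every probe tested (0.0536).

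In all, 23 of the 14686 genes and unnamed probes tested passed a Benjamini-Hochberg adjusted p of 0.05 by limma, 8 higher and 15 lower in knockout, and 1093 had an unadjusted p under 0.05. With median scaling in place of quantile normalization the split was 4 higher and 15 lower. Of the 23, 16 had a gene symbol, 2 higher (Kdm5d and Slc2a3) and 14 lower, and 2 of these 16 (Xist and Kdm5d) were X- or Y-linked. In all 23 the genotypes did not overlap, which held for 12.1% of everything tested, against 10% by chance. The 7 unnamed probes, for which no symbol was at hand, had 6 members higher in knockout. ILMN_2449264 rose most among them, at least 7.59-fold (adjusted p = 0.00959), and ILMN_2770081 was the 1 that fell (log2 change -1.90).

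The other falling genes span several functions. Zfp593, a zinc finger gene, fell (log2 change -3.28, SE 0.39, adjusted p = 0.0287) and Ephx2, the soluble epoxide hydrolase, fell too (-2.61, SE 0.35, adjusted p = 0.0410). Cma1, a mast cell chymase, fell at least 6.58-fold, Camk1d, a calcium/calmodulin-dependent kinase, at least 3.26-fold, and the annexin Anxa1 at least 3.09-fold. BC048679 fell at least 2.65-fold and the chemokine Cxcl5 at least 2.36-fold, and the probe that stood for each of these 5 genes was detected on 0 knockout arrays. Myocd, a coactivator of muscle genes, fell as well (-1.60, SE 0.21, adjusted p = 0.0401). Mgarp (-1.34) and Dmrta2 (-1.16), a doublesex-related transcription factor, also fell (both adjusted p = 0.0230), and these 2 were named after their values were seen because they complete the 16. Other probes of the same genes gave smaller changes: Zfp593 -1.40, Xist -1.32, Myocd -0.41, and Camk1d -0.35 and 0.14, the last of opposite sign. Zfp593 was detected on 1 of 3 knockout arrays, so the size of its fall depends on the background offset (-2.41 with an offset of 50). The calls of Camk1d and Myocd were lost with the mean of probes (adjusted p = 0.291 and 0.281).

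The named genes that follow had the smallest p-values among those higher in knockout and did not pass. Hmga2-ps1 was 2.13 higher (SE 0.35), the tight junction gene Cldn11 1.97 higher (SE 0.35) and the forkhead gene Foxq1 1.88 higher (SE 0.35). Foxq1 was detected on 1 of 3 wild type arrays, and was 1.18 higher with an offset of 50. Emp1, undetected in wild type, was at least 3.25-fold higher. B3gnt8 and Sptb, also undetected in wild type, were at least 1.80-fold and 1.58-fold higher. Vat1l was 0.96 and Ahnak 0.85 higher. Rbm6 was 1.13 higher by its brightest probe and 0.23 higher by the mean of its probes. Together with Eif2s3y these genes had adjusted p-values from 0.0601 to 0.144.

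**Figure D3:**
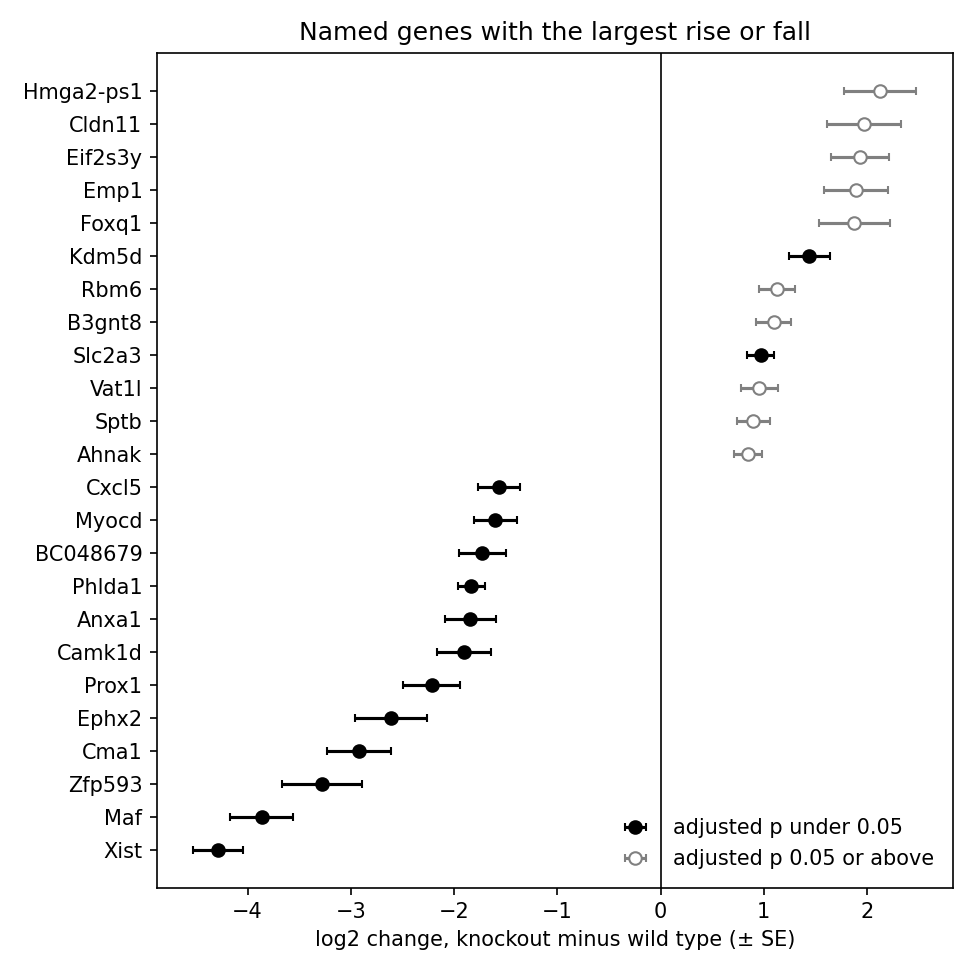
Log2 change, knockout minus wild type (horizontal axis, ± SE), of the 12 named genes with the largest fall and the 12 taken for a rise. Filled points passed an adjusted p of 0.05 and open points did not. Xist and Maf lie farthest to the left, at -4.28 and -3.86.

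Calls depended on each array. Without wild type 1, 2 or 3 the count was 2, 1 or 3, and without knockout 1, 2 or 3 it was 6, 3 or 3, in each case all among the 23. Xist passed in 6 of these 6 fits, Phlda1 in 5, Maf in 4, Ephx2 in 1 and the other 12 named genes in 0, Prox1 included. A stricter filter on dim probes gave 69 calls, 22 of them among the 23. No filter gave 6, with Xist, Maf, Phlda1, Cma1 and Mgarp as the named genes. Without the variance trend the calls of Prox1, Ephx2, Dmrta2, Mgarp, Slc2a3 and Kdm5d were lost (adjusted p 0.0630 to 0.168). With a background offset of 50 the calls of Kdm5d, Camk1d, Anxa1, BC048679 and Cxcl5, each undetected in 1 genotype, were lost (adjusted p 0.0503 to 0.0692). Their log2 changes were then 0.82, -1.21, -1.15, -1.04 and -0.92.

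Among lens placode regulators, 13 of 19 tested members were lower in knockout. Only Maf and Prox1 passed over all genes. Adjusted over the list alone, 3 passed, with Mab21l1, a gene needed for lens formation, as the third (log2 change -0.82, SE 0.16, adjusted p = 0.165 over all genes). Sox11 was 0.38 higher (SE 0.13, adjusted p = 0.556). The SOX factor Sox2 (-0.86, SE 0.32, adjusted p = 0.601) and the homeobox gene Six3 (-0.80, SE 0.38, adjusted p = 0.718) were lower, Otx2 (0.77, SE 0.31, adjusted p = 0.631) and Mab21l2 (1.01, SE 0.49, adjusted p = 0.726) were higher, and these 4, named after their values were seen, did not pass. The list as a whole (median -0.13) did not pass camera, a competitive gene set test (adjusted p = 0.0701), and passed without wild type 3 (adjusted p = 0.0116), with no background correction (0.0499) and with a variance trend in camera (0.0494), the last chosen after the data were seen.

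Crystallins and lens fibre genes were mostly near the detection limit, with 13 of 28 tested and 8 of these lower. Adjusted over the list alone, Cryge (-2.39, SE 0.48) and Crygb (at least 2.03-fold) were lower and Mip, a lens fibre water channel, was higher (1.91, SE 0.49), and 0 passed over all genes. Cryge was detected on 1 knockout array, and was -1.65 with an offset of 50. Crybb3 was at least 1.66-fold lower and did not pass. The list did not pass (camera adjusted p = 0.543).

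Placode genes of other kinds did not pass as a group. Of 15 preplacodal and other placode genes tested, 10 were higher in knockout (median 0.18, camera adjusted p = 0.0701, and 0.0137 without wild type 2 and 0.0260 with median scaling). Adjusted over the list alone, Foxi2 (1.65, SE 0.36) and the LIM homeobox gene Isl1 (1.00, SE 0.22) were higher and Dlx3 was lower (-0.62, SE 0.17), and 0 passed over all genes. Msx2 was 0.39 higher (SE 0.18). Among 34 surface ectoderm and epidermal genes, 19 were lower (median -0.19, camera adjusted p = 0.368). Tfap2b (1.03, SE 0.21) passed over the list alone, and Tfap2a (-0.59), Ovol1 (-0.96) and Epcam (-0.38) did not.

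Sterol biosynthesis genes fell as a group, with 16 of 17 tested members lower (median -0.35, camera adjusted p = 0.000198). This call was lost with an estimated correlation between genes (adjusted p = 0.338 with an estimated correlation). No member passed over all genes, and 2 passed when adjusted over the list alone, the sterol enzymes Msmo1 (-1.14, SE 0.31) and Sqle (-0.71, SE 0.19, but -0.23 by the mean of its probes). Without wild type 1 the median was -0.18 and the group's adjusted p 0.0160. Insig1, which restrains sterol synthesis, was -0.58 (SE 0.18) and the X-linked Ebp -0.47 (SE 0.18). Ebp was detected on 2 knockout arrays, and was -0.25 with an offset of 50.

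Cell cycle genes fell slightly as a group by camera, with 33 of 46 lower, a median of -0.13 and adjusted p = 0.0356 (adjusted p = 0.338 with an estimated correlation). No member passed by either adjustment, and the largest differences by p were Cenpa (-0.47), Cdc25c (-0.66), Mcm4 (-0.28) and Bub1b (-0.63). The direction of Mcm4 turned when all its probes were averaged (0.047). The group's adjusted p was 0.0866 without wild type 2, 0.161 without wild type 3, 0.164 without knockout 2 and 0.0671 without knockout 3.

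Optic vesicle and neuroepithelium markers rose as a group, with 13 of 17 higher (median 0.37, camera adjusted p = 0.0105), and 0 members passed over all genes. The call was lost with an estimated correlation (adjusted p = 0.338 with an estimated correlation). Adjusted over the list alone, Bmp4 was higher (0.90, SE 0.22) and Sfrp2, a secreted Wnt antagonist, was lower (-1.13, SE 0.16, adjusted p = 0.0508 over all genes), against the direction of the list. Fgf15 was 0.73 higher (SE 0.23) and Tbx5 1.62 higher (SE 0.57, and 0.92 by the mean of its probes). The list's mean was 7.92 in knockout 2 and 7.85 in knockout 3, but 7.22 in knockout 1 against 7.09 to 7.35 in wild type. Red cell marker means were highest on the same arrays, 6.85 in knockout 2 and 7.49 in knockout 3, against 6.20 in knockout 1. The group's adjusted p was 0.158 without knockout 2 and 0.0671 without knockout 3.

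Neuronal differentiation genes rose as a group too, with 13 of 17 higher (median 0.23, camera adjusted p = 0.0264, adjusted p = 0.480 with an estimated correlation). Isl1, which is also in the placode list, and Onecut2 (1.01, SE 0.24) passed over the list alone, and 0 passed over all genes. Insm1 was 0.54 and Ebf1 0.48 higher. Onecut2 and Insm1 were each detected on 1 of 3 wild type arrays, and were 0.60 and 0.29 higher with an offset of 50. The list's mean was 6.33 in knockout 2 and 6.24 in knockout 3, but 6.07 in knockout 1 against 5.70 to 6.12 in wild type. Knockout 2 and 3 also had the higher red cell marker means of the knockout arrays (6.85 and 7.49, against 6.20 in knockout 1). Wild type 1, at 6.69, was close to knockout 2. The group's adjusted p was 0.126 without wild type 3, 0.158 without knockout 2 and 0.0671 without knockout 3.

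Red cell markers did not differ past the threshold as a list. Their mean over the list was 6.85 in knockout 2 and 7.49 in knockout 3, 6.20 in knockout 1 and at most 6.69 in wild type. The globin genes Hba-a1 (2.02, SE 0.75), Hba-x (1.83, SE 0.71) and Hbb-bh1 (1.54, SE 0.81) were higher in knockout, and Tal1 was lower (-0.70, SE 0.36), with adjusted p-values of 0.585 to 0.772. The list, with 6 of 10 members higher (median 0.47), did not pass (camera adjusted p = 0.368). Head mesenchyme and neural crest markers had 16 of 22 members higher (median 0.15, camera adjusted p = 0.0777). That list passed with every probe tested (adjusted p = 0.00989), with no background correction (0.0499) and with a variance trend in camera (0.0499), a setting chosen after the data were seen. Adjusted over the list alone, Tfap2b and the galectin Lgals1 (0.67, SE 0.14) were higher and the receptor Erbb3 was lower (-0.98, SE 0.27), and the collagen Col3a1 was 0.93 higher (SE 0.35). Erbb3 was detected on 2 of 3 knockout arrays, and was -0.59 with an offset of 50. Endothelial markers had 6 of 8 higher (median 0.086, camera adjusted p = 0.546). Their mean over the list was 6.54 in knockout 2 but 6.07 in knockout 3, against 5.95 to 6.34 in wild type. Fli1 was 0.43 higher and turned to -0.11 when its probes were averaged. Cldn5 was 0.43 higher (SE 0.61), at 4.92 in knockout 1 against 7.04 and 6.75 in knockout 2 and 3. Cd34 was 0.20 higher, and Ramp2 was -0.23, at 5.77 in knockout 2 but 4.87 in knockout 3.

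In the FGF and ERK pathway, Phlda1 fell, 15 of 31 members were lower, and the list did not pass (camera adjusted p = 0.10). Its median (0.0069) was above 0 while its mean (-0.21) and the test pointed down. Flrt2 was -0.81 (SE 0.22), the ETS factor Etv1 -1.35 (SE 0.39) and Fgf15 0.73. In the Wnt pathway, 20 of 43 members were lower (median 0.047, mean -0.047, test down, camera adjusted p = 0.535), and 6 passed when adjusted over the list alone. Sfrp2 (-1.13), Dkk3 (-1.08, SE 0.19), Wnt5a (-1.32, SE 0.34, but -0.48 by the mean of its probes), Lgr5 (at least 1.95-fold) and Wnt7a were lower, and Dkk1 was higher. In the retinoic acid pathway, 4 of 10 were lower (median 0.11, mean -0.24, test down, camera adjusted p = 0.762). The retinol transporter Stra6 (-2.37, SE 0.41) and the retinaldehyde dehydrogenase Aldh1a3 (-1.20, SE 0.22) were lower and passed over the list alone, and Crabp2 was 0.38 and Rarb 0.69 higher. Stra6 was detected on 1 knockout array, and was -1.70 with an offset of 50. None of these Wnt or retinoic acid genes passed over all genes. In the BMP and TGF-beta pathway, 20 of 38 were higher (median 0.012, camera adjusted p = 0.524). Besides Bmp4, Tgfb2 was 1.32 and Fst 0.39 higher and Tgfbr3 was -1.03. In the Notch pathway, 9 of 18 were higher (median -0.00068, mean 0.028, test up, camera adjusted p = 0.937). Its members by smallest p were Mfng (at least 1.14-fold lower), Dlk1 (0.37), Hey2 (0.57) and Jag1 (-0.60).

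The matrix and shape gene lists did not pass. Of 48 extracellular matrix genes and receptors, 27 were higher (median 0.064, mean -0.058, test up, camera adjusted p = 0.958). The collagen Col13a1 (-1.93, SE 0.33) and tenascin C, Tnc (-1.72, SE 0.31), were lower and passed over the list alone but not over all genes. Col18a1 was 0.67 and Has2, a hyaluronan synthase, -0.76. Of 43 apical constriction and cytoskeleton genes, 29 were lower (median -0.080, camera adjusted p = 0.446). Daam1 was -0.99 (SE 0.29, and -0.48 by the mean of its probes), Shroom1 -1.31, Msn 0.51 and Ezr -0.33, and 0 passed by either adjustment. Shroom1 was detected on 1 knockout array, and was -0.87 with an offset of 50.

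The remaining lists did not pass in the main analysis. Of 28 p53 target and cell death genes, 18 were lower (median -0.098, camera adjusted p = 0.118), among them Plk2 (-0.76), Phlda3 (-0.35), Tnfrsf10b (-0.90) and Sesn2 (-0.47). The p53 list passed with every probe tested (adjusted p = 0.0224) and with the mean of probes (0.0427). Of 28 glycolysis and hypoxia genes, 16 were higher (median 0.031, camera adjusted p = 0.661). Slc2a3 passed there, Eno2 was 0.74 higher, and Ddit4 (-0.41) and the glucose transporter Slc2a1 (-0.36) were lower. Of 13 immediate early and heat shock genes, 8 were lower (median -0.094, camera adjusted p = 0.661). Klf6 (0.64, SE 0.14) passed over the list alone, and Egr1 (-1.25), Hspb1 (-0.24) and Dusp1 (-0.45) did not. Egr1 was detected on 1 knockout array, and was -0.76 with an offset of 50. Of 39 cytosolic ribosomal protein genes, 24 were lower (median -0.040, camera adjusted p = 0.368), among them Rplp0 (-0.73), Rpl4 (-0.39), Rps27 (-0.33) and Rps24 (-0.29). Of 56 oxidative phosphorylation genes, 34 were lower (median -0.051, camera adjusted p = 0.368). Ndufa2 (0.74) and Ndufa8 (0.72) were higher, and Ndufa6 (-0.89) and Atp5g3 (-0.38) were lower.

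Of the 23 lists, 4 passed by camera, and 0 passed with an estimated correlation or by fry, a rotation test of whether the genes of a list move one way. With undetected members at their bound, the list medians were as given, except p53 targets and cell death at -0.097.

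**Figure D4:**
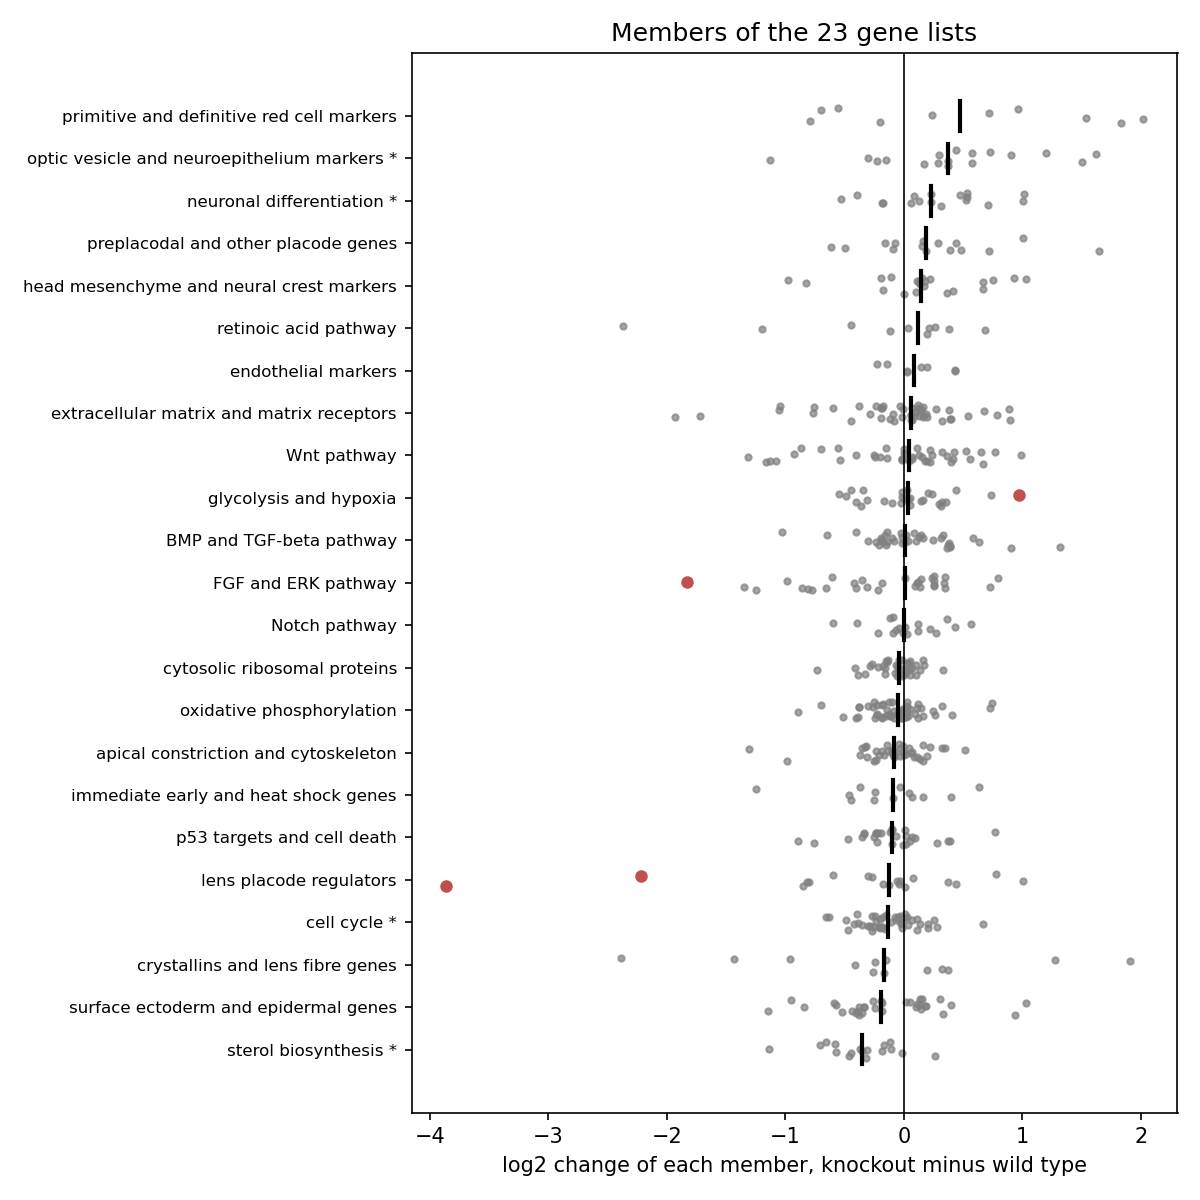
Log2 change, knockout minus wild type (horizontal axis), of each tested member of the 23 gene lists. Vertical bars are list medians, red points passed an adjusted p of 0.05 over all genes, and an asterisk marks the 4 lists past the threshold by camera. Sterol biosynthesis has the lowest median, -0.35, and Maf and Prox1 stand apart in the lens placode list.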

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

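The runs without X- and Y-linked genes and with a variance trend in camera were chosen after the data were seen, and the others before. The 23 changed genes became 6 with no filter (1 higher, 5 lower), where more probes share the adjustment. They became 69 with the stricter filter (23 higher, 46 lower), where 8640 are tested. That filter asks for detection on all 3 arrays of a genotype. It thus uses the labels tested and can favour probes high in 1 genotype, and why the count rose was not tested. Higher genes numbered 4 with median scaling, 5 without the variance trend and 13 with array weights, against 8, and the cause was not tested. Leaving out 1 array, which leaves fewer samples, gave 1 to 6 changed genes, 0 to 2 higher and 1 to 4 lower. The other alternatives gave 18 to 34 changed genes (34 with array weights), and 21 without X- and Y-linked genes. Median scaling moved the median change of all genes to -0.15, so its changes are relative to that. The replicate block left 1 changed gene, 0 higher and 1 lower, and 3 lists. No sign was seen that replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at -0.05 to -0.02 and 0 of 6 arrays correlated best with its own number. With 3 such pairs a pairing cannot be excluded. Pairing by BeadChip position was not tested. Deviations correlated at 0.088 for wild type 1 and knockout 3 (positions A and B). They correlated at 0.056 for wild type 3 and knockout 2 (C and D) and 0.068 for wild type 2 and knockout 1 (E and F). All other pairs between genotypes were negative, also the adjacent B and C (-0.036) and D and E (-0.024). These values are small, and a pairing by position stays open.

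The 16 named genes past the threshold kept their direction in all 301 comparisons and their call in 168. Maf passed in 16 of 19 (adjusted p 0.000335 to 0.104), Phlda1 in 17 of 19 (0.000335 to 0.0652), Prox1 in 10 of 19 (0.00716 to 0.207) and Xist in 18 of 18. Kdm5d passed in 4 of 17 and Camk1d in 7 of 19, the fewest, Slc2a3, Anxa1, BC048679 and Cxcl5 in 8 of 19 each, and the other 6 in 10 to 12. Pax6 kept its direction and did not pass in any setting (log2 change -0.98 to -0.57). The 4 lists became 1 with the stricter filter, 1 to 4 without 1 array, and 0 with an estimated correlation or fry. These 4 kept their direction in 80 comparisons and their call in 57, and 10 comparisons brought another list past the threshold. Sterol biosynthesis passed in 18 of 20 settings, the optic vesicle list in 15, neuronal differentiation in 14 and cell cycle in 10. Signal over background limits dim genes, such as the crystallins, of which 2 of 13 tested list members have only a bound. Changes of named genes detected on only 1 or 2 arrays of a genotype were all smaller with an offset of 50.

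Directions turned only in results that had not passed, and the cause was not tested. With the mean of a gene's probes, Mcm4 was 0.047 and Fli1 -0.11. That setting also changed the size, not the direction, of Msx2 (0.15), Tfap2a (-0.92), Dlk1 (0.10), Rarb (0.31), Cenpa (-0.31), Cdc25c (-0.29), Ebf1 (0.31), Rps24 (-0.11) and Xist (-2.80). With the stricter filter, adjusted p-values of turned lists were crystallins 0.248, surface ectoderm 0.918, extracellular matrix 0.837 and immediate early genes 0.996. The extracellular matrix list also turned with median scaling (0.653), mean of probes (0.734), every probe (0.306), the replicate block (0.882), fry (0.679), and without 1 array (0.712, 0.862 and 0.954 without knockout 1, wild type 2 and knockout 2, in a range to 0.972). The Notch list turned with the authors' table (0.939), array weights (0.608), mean of probes (0.996), every probe (0.975), fry (0.989), and without 1 array (0.574, 0.963, 0.996 and 0.999 without knockout 1, wild type 1, wild type 3 and knockout 3, in a range from 0.392). Without knockout 2 the Wnt and endothelial lists turned (0.832 each, in ranges without 1 array from 0.135 and from 0.269 to 0.850), and without knockout 1 the ribosomal (0.724, range 0.104 to 0.850) and oxidative phosphorylation lists (0.857, range from 0.104).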

Other observations

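Below the threshold lay 15 genes and probes with an adjusted p between 0.05 and 0.1, of which 13 had a symbol, 6 higher and 7 lower in knockout. Of those not yet described, named after their values were seen, Khdrbs2, an RNA-binding protein gene, had a log2 change of -2.25 (SE 0.33, limma adjusted p = 0.0571). Antxr1, a receptor that binds matrix proteins, was -1.53 (SE 0.22, adjusted p = 0.0571). Cadps2, a gene of vesicle release, was -1.89 (SE 0.30, adjusted p = 0.0859), Fam83f was -2.04 (SE 0.34, adjusted p = 0.0992), and Gm11149, undetected in knockout, was at least 1.77-fold lower (adjusted p = 0.0882). Khdrbs2 was detected on 2 and Fam83f on 1 of 3 knockout arrays, so the sizes of their changes may depend on the background offset. The X-linked Pbdc1 was -1.47 (SE 0.23, adjusted p = 0.0859), and it was left out of the genes tested for escape from X inactivation because its value had been seen. In these 6 genes the 3 knockout values lay below the 3 wild type values.

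Tests in the paragraphs that follow were partly chosen after the result was seen: the splits for changed genes, the share on X and Y, the arrays where sex and genotype part, and the tests of the Pax6 signal. The others were written before. The rules by which the Rax test and the optic vesicle array means are read as open were also set after their values were seen.

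The first pattern is that Xist and Y-linked genes separated the genotypes along with the 23 changed genes. If the wild type embryos were female, genes that escape X inactivation would be higher in them. By sign, 5 of 6 such genes were higher in wild type, with a median change of -0.28, against -0.03 for 332 X-linked genes. Kdm5c was -1.24 (SE 0.33) and Eif2s3x -0.71 (SE 0.29). Utp14a (-0.33, SE 0.30), Kdm6a (-0.22, SE 0.28) and Ddx3x (-0.05, SE 0.13) lay nearer to 0, Mid1 was 0.16 (SE 0.30), and none of the 6 passed. Dosage of the sex chromosomes is argued against as the direct cause for most changed genes with a symbol, since 14 of the 16 lie on other chromosomes. The 12.5% of the 16 that lie on X or Y are a larger share than among all genes tested. Of the 9618 genes with a symbol tested, 332 lay on X and 4 on Y. The 7 unnamed probes have no known chromosome. An indirect effect of sex on the changed autosomal genes, Maf and Prox1 included, cannot be told apart from genotype, because sex by Xist and genotype part on 0 arrays. The 10 splits of 6 arrays are too few for a share under 0.05: the real split gave 23 genes and the highest other 1, so 1 split reached the real count.

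The second pattern is that Pax6 signal stayed high in knockout, 1.67-fold lower by its brightest probe. Exchanged labels stay open: the groups lay apart by 3.21 in Maf and 1.49 in Prox1, but both genes were chosen among the 23 called between these labels, in all of which the groups do not overlap, and an exchange of whole groups would leave no overlap either. Optic vesicle tissue, which also expresses Pax6, may add signal if its cells in knockout hold Pax6 RNA that the probes read, which is not known here. But Rax, at 5.69 ± 0.17 in wild type and 6.07 ± 0.35 in knockout, was 1.31 standard errors higher, below the bound of 2 set for it, which neither shows nor excludes a small rise. RNA still made from the mutant allele may also be read, and the largest difference between the Pax6 probes, 0.33 (SE 0.39), leaves this open because neither the deleted part nor the places of the probes are known here.

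The third pattern is the shift of gene lists, optic vesicle markers up and sterol biosynthesis genes down. A trend with intensity is argued against for both: the optic median lay at percentile 100 and the sterol median at percentile 0 of 10000 random lists matched on intensity. A single deviating array as the whole cause is argued against only for the sign of the sterol median, which stayed below 0 without each array in turn. Without wild type 1 the median moved from -0.35 to -0.18 (camera adjusted p = 0.0160). The sterol list passed camera without each array, but at the preset correlation of 0.01. With the correlation estimated for this list, 0.11, it did not pass on all 6 arrays (camera adjusted p = 0.338). Optic vesicle tissue in the knockout dissections may contribute to the first shift, and 17 neuronal genes outside that list had a median of 0.23. But the list's lowest knockout array mean was below its highest wild type mean by 0.13 (difference -0.13), less than the SD of 0.29. The overlap set beforehand as counting against it was thus within the spread, and this stays open. The list and the red cell markers (6.85 and 7.49) were both highest in knockout 2 and 3, but wild type 1 was close in red cell markers (6.69). Endothelial and head mesenchyme markers were highest in knockout 2 (6.54 and 7.77). In knockout 3 (6.07 and 7.48) they lay below wild type 1 (6.34 and 7.55). The ectoderm may also express some of the genes of the optic vesicle list. For lists the real split gave 4 and the highest other 3, with 1 of 10 splits as large, again too few for a share under 0.05, and the 3 splits with 3 lists all grouped knockout 1 with wild type 1.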
